A study of Mus musculus with 32 samples.

How the data were processed

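The series measured gene expression by RNA sequencing in 32 libraries from 16 C57BL/6 mice. Each mouse gave 1 library of LSK cells, the lineage-negative, Sca-1 and Kit positive bone marrow fraction that holds hematopoietic stem cells, and 1 library of progenitor cells, whose gate is not described in the labels. Kat7, also called Hbo1, encodes the catalytic subunit of a histone acetyltransferase complex. It was deleted in adult mice either by a tamoxifen-activated Cre (CreER) or by an interferon-responsive Cre switched on with polyIC (Mx1Cre). The 8 groups held 4 libraries each: knockout or control, for each Cre line and cell population. Titles and design describe the controls as heterozygous, with 1 floxed allele, and the titles state that this allele was deleted. The treatment protocol calls the controls wild type, so their exact genotype rests on the titles. Each Cre line came with its own treatment and its own mice.

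Per the labels' protocols, 50 ng of RNA from sorted cells was made into TruSeq libraries and sequenced as paired-end 80 bp reads on a NextSeq500. Per the submitters' processing notes, reads were counted per gene with featureCounts on mm10. The version, the aligner, the annotation and the strand setting are not given in the sources used here. The deposited values are whole-number counts per gene, not normalized, for 27179 genes with Entrez identifiers, together with the exon length of each gene. The column of each of the 32 libraries in the table of the whole series was identical to the library's own table. Symbols were found for 25275 genes from a RefSeq gene table of the same genome build. The other 1904 genes carried 3.92% of the counts and kept their identifiers. Total counts per library ran from 7275277 to 18409271, with a median of 12207444. Reads without molecular identifiers are not independent molecules, so counting limits cover counting error only. Genes overlapping each other or an antisense partner, and close paralogs, may share counts.

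Counts were analysed with edgeR 4.0.16 in R 4.3.3, with TMM normalization, its filter on low counts (at least 10 counts in enough libraries and 15 in total), the quasi-likelihood test and Benjamini-Hochberg adjustment, at a threshold of 0.05. Each cell population was fitted with its 16 libraries, and comparisons of LSK with progenitor cells with all 32. Group values are CPM, the share of a library's counts scaled to a common total with TMM. Log2 fold changes are knockout over control, with standard errors (SE) from the same test, and n is 4 libraries per group unless stated. In all 12 comparisons were made, 5 in each cell population and 2 across them. A total of 29 gene lists, fixed before the data were examined, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, which compares a list with the other genes. The alternative fry tests whether the genes of a list move, on balance, 1 way, and does not compare the list with other genes. The lists were HBO1 complex subunits, other histone acetyltransferases, HSC transcription factors, long-term HSC markers, HSC quiescence genes, Hoxa and Hoxb genes, multipotent and lymphoid priming genes, megakaryocyte genes, erythroid genes, mast cell, basophil and eosinophil genes, neutrophil granule genes, monocyte and macrophage genes, dendritic cell genes, B cell genes, T and NK cell genes, endothelial and stromal genes, MHC class II genes, STAT5 and cytokine response genes, interferon-stimulated genes, immediate early genes, p53 target genes, BCL2 family genes, oxidative phosphorylation genes, glycolysis genes, ribosomal protein genes, ribosome biogenesis genes, S phase genes, G2 and M phase genes and replication origin licensing genes. List tests in comparisons other than knockout against control were added after the data were examined.

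Genes eligible to be named were fixed by a rule before the data were examined. HBO1 complex subunits were eligible. Each cell population gave the 8 largest rises and falls in the mean of both Cre lines. These were ranked among genes called in both Cre lines separately with the same sign. Each single comparison gave the 4 largest rises and falls among its called genes. Each list gave up to 4 members with the lowest adjusted p. Differences between Cre lines, between cell populations and between control groups gave the 4 called genes with the lowest p in each direction. The ranks by size took genes with a mean of at least 1 log2 CPM. Unnamed gene models, Xist and Y-linked genes were left out of the ranks. The text names part of the eligible genes, chosen after their values were seen, and some results are not reported here. For a group with no count of a gene, the fold is a bound against 3 counts over the group.

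Alternatives fixed beforehand were size factors of DESeq2 1.42.0 in edgeR, the DESeq2 and limma-voom tests, no filter or a filter of 1 CPM in 4 libraries, sex as a covariate, the replicate number or the mouse as a block, the 8 compared libraries alone, a test against a fold of 1.5, each library or mouse left out in turn, and camera with an estimated correlation or fry. Added after the data were examined were removal of a lowess trend (span 0.3) of each library on log2 exon length, omission of LSK CreER knockout libraries 2 and 3, exchange of those libraries, omission of progenitor Mx1Cre control 1, and the remaining settings for correlations. Same-numbered LSK and progenitor libraries within a group carry the same mouse number in the labels and were taken as paired. The LSK CreER knockout libraries 2 and 3 went against this, with correlations of -0.094 and -0.063, each closest to the progenitor library of the other. LSK Mx1Cre knockouts 2 and 3 were also closest to another mouse's progenitor library, numbers 1 and 4. They correlated positively with their own, at 0.4 and 0.158. LSK Mx1Cre knockout and control libraries of the same number also deviated together, with correlations from 0.147 to 0.259. The scripts were tested on simulated counts in which 100 genes changed 2-fold and 100 changed 1.5-fold. In the LSK comparison over both Cre lines, 97% of 2-fold and 87% of 1.5-fold changes were recovered among genes tested, with 12 of 13806 unchanged genes called. In progenitors the corresponding values were 94% and 57%, with 9 of 13423. For the CreER comparison alone they were 90% and 56% in LSK cells, and 71% and 19% in progenitors. For Mx1Cre alone they were 92% and 59% in LSK cells, and 81% and 20% in progenitors. These simulated libraries had no length trend and no paired deviations, unlike the real ones. The simulated changes were the same in both Cre lines, while real effects differed for 616 genes in LSK cells. Recovery over both Cre lines therefore holds for equal effects. With a length trend simulated in 3 LSK Mx1Cre knockout libraries, 50 of 13830 unchanged genes were called, against 9 of 13806 without it. Figures were drawn with matplotlib.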

Results

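RNA of LSK and progenitor cells from the same 16 mice was sequenced to compare cells lacking Kat7 with control cells, after deletion by CreER or by Mx1Cre. The title of the series names stem cell quiescence and self-renewal as its subject. The 4 libraries of a group came from 4 mice. Total counts were lowest in progenitor Mx1Cre knockout library 4 (7275277) and highest in LSK Mx1Cre knockout library 2 (18409271). CreER groups held 3 females and 1 male and Mx1Cre groups 2 of each, per the labels.

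Kat7 (Entrez 217127, chromosome 11, 95271853 to 95310246 on mm10) was nearly absent from all 16 knockout libraries. In LSK cells it fell from 67.3 ± 10.2 CPM (SD, n = 4) in CreER controls to 0.846 ± 0.279, or 1.26% of control, and from 70.6 ± 4.62 in Mx1Cre controls to 1.34 ± 0.299, or 1.9%. In progenitors it fell from 71.5 ± 4.58 to 0.454 ± 0.433 CPM with CreER (0.636%) and from 61.9 ± 15.5 to 1.47 ± 0.179 with Mx1Cre (2.38%). The highest knockout library held 1.69 CPM and the lowest control 39.3 CPM, which was progenitor Mx1Cre control 1. Of the 10 measured HBO1 complex subunits, Kat7 fell and Jade2, a scaffold subunit, rose in both populations, by 0.38 ± 0.07 (log2, SE) in LSK cells (edgeR, Benjamini-Hochberg adjusted p = 0.000892) and by 0.52 ± 0.14 in progenitors (adjusted p = 0.0318). No other subunit passed the test. As a list the subunits were not called (camera adjusted p = 0.857 in LSK cells and 0.724 in progenitors). Of the 9 other histone acetyltransferases, 1 rose in LSK cells and 0 in progenitors, with camera adjusted p of 0.696 and 0.568.

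**Figure D1:**
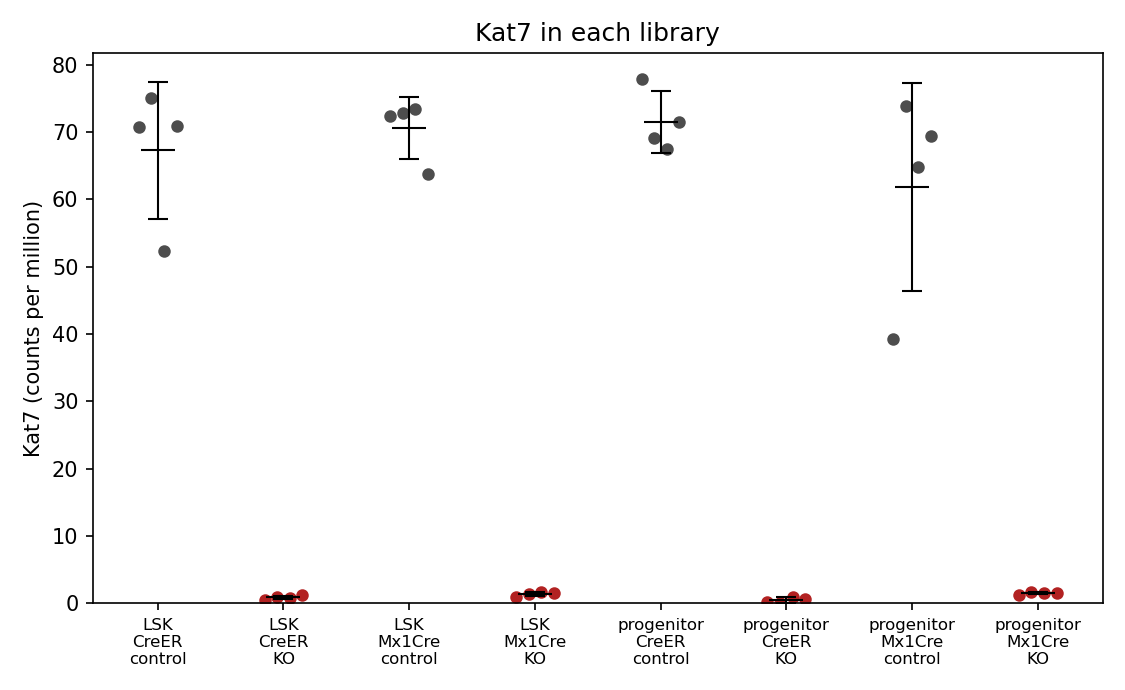
Kat7 in each library, in CPM, by group. Points are libraries, bars the mean ± SD of 4 libraries; the knockout libraries lie at or below 1.69 CPM and the controls at or above 39.3 CPM.

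In knockout LSK cells, genes that fell included many of stem cell identity and of the megakaryocyte and mast cell lineages, and genes that rose many of oxidative phosphorylation. Of the 16 gene lists that camera called with the preset correlation, 0 were called with an estimated correlation. Tek, the angiopoietin receptor, fell by 2.39 ± 0.26 (log2, SE) over both Cre lines. The transcription factor genes Hoxa9, Gata2 and Gfi1b fell by 1.24 ± 0.09, 1.21 ± 0.11 and 1.61 ± 0.17. Gata2 stood at 460 ± 39 CPM (SD) in CreER controls and 256 ± 43.7 in CreER knockouts, and at 206 ± 35.3 and 69 ± 14.3 with Mx1Cre. Hoxa9 went from 46.6 ± 6.54 to 25.4 ± 4.43 CPM with CreER and from 40.5 ± 2.64 to 13.3 ± 1.31 with Mx1Cre. The edgeR test with Benjamini-Hochberg adjustment gave adjusted p of at most 4.03e-06 for these genes. Tek, Gfi1b and Hoxa9 had called interaction terms (log2, Mx1Cre minus CreER) of -2.61, -1.57 and -0.74. In all, 3927 of 14102 genes tested were called, 1904 higher and 2023 lower, and 530 against a fold of 1.5, 84 higher and 446 lower.

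Among the 22 HSC transcription factors 14 fell and 2 rose, the same counts as when adjusted over the list alone (camera adjusted p = 9.99e-07, and adjusted p = 0.385 with an estimated correlation). Of the 20 long-term HSC markers 11 fell, also 11 when adjusted over the list alone, among them the endothelial and stem cell surface genes Eng (-0.80 ± 0.09) and Robo4 (-1.95 ± 0.24). This list had camera adjusted p = 4.21e-05, and adjusted p = 0.385 with an estimated correlation. Eng and Robo4 had called interaction terms (log2, Mx1Cre minus CreER) of -0.80 and -2.03. The HSC quiescence genes went both ways, with 7 of 24 lower and 4 higher (8 and 5 adjusted over the list alone), and camera adjusted p = 0.0258 (adjusted p = 0.45 with an estimated correlation, 0.0505 with the gene length trend removed and 0.0649 without CreER knockouts 2 and 3). Egr1, an immediate early factor of this list, fell by 1.59 ± 0.29. Several members, among them Tek, Gfi1b, Egr1, Tal1, Gata2, Erg, Meis1, Hoxa9 and Satb1, are remembered as genes named in the published study of these mice, so the lists that hold them are not independent evidence of their direction. All 6 called Hoxa and Hoxb genes of 11 measured fell (7 adjusted over the list alone), Hoxa7 by 1.04 ± 0.09, with camera adjusted p = 0.000122 (adjusted p = 0.385 with an estimated correlation). Of the genes given with a change in this paragraph, Egr1 had the highest adjusted p of the edgeR test with Benjamini-Hochberg adjustment, 0.000571.

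Lineage genes moved apart in LSK cells. Of 15 megakaryocyte genes 10 fell and 1 rose, the same when adjusted over the list alone (camera adjusted p = 0.000239, and adjusted p = 0.385 with an estimated correlation). Of the platelet integrin pair, Itga2b fell by 1.27 ± 0.08 and Itgb3 rose by 0.73 ± 0.10. Of 15 mast cell, basophil and eosinophil genes 7 fell (8 fell and 1 rose adjusted over the list alone), such as the interleukin-33 receptor gene Il1rl1 (-1.15 ± 0.13), with camera adjusted p = 0.00345 (adjusted p = 0.385 with an estimated correlation). Erythroid genes were mixed, with 3 of 19 higher and 6 lower (3 and 8 adjusted over the list alone). The erythroid factor Gata1 fell by 1.39 ± 0.16 and the carbonic anhydrase gene Car1 by 1.84 ± 0.31, while the list was not called (camera adjusted p = 0.132). Il1rl1, Gata1 and Car1 had called interaction terms (log2, Mx1Cre minus CreER) of -1.57, -1.87 and -3.28. Most of each of these 3 falls therefore came with Mx1Cre. Multipotent and lymphoid priming genes had 9 of 18 lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.0206, and adjusted p = 0.426 with an estimated correlation). Of 14 T and NK cell genes 7 fell and 1 rose (7 and 2 adjusted over the list alone), with camera adjusted p = 0.0404 (adjusted p = 0.385 with an estimated correlation, 0.0519 to 0.0748 without CreER knockout 3, CreER controls 2 and 3 or Mx1Cre controls 1, 2 and 3, each left out alone, and 0.09 without CreER knockouts 2 and 3). Of 20 neutrophil granule genes 7 rose (9 adjusted over the list alone) and 0 fell, with camera adjusted p = 0.00345 (adjusted p = 0.598 with an estimated correlation). Ms4a3, a granulocyte-monocyte progenitor gene, rose by 1.09 ± 0.19, and S100a8, a calgranulin, by 1.69 ± 0.38, with the highest adjusted p of the genes named here (edgeR, Benjamini-Hochberg, 0.00302). Of 22 monocyte and macrophage genes 4 rose and 1 fell (4 and 0 adjusted over the list alone), with Itgam up by 0.91 ± 0.12 and the mannose receptor gene Mrc1 by 2.33 ± 0.34, and the list was not called (camera adjusted p = 0.125).

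Lists of metabolic and cell cycle genes were higher in knockout LSK cells. Of 26 oxidative phosphorylation genes 21 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 change of 0.35 and camera adjusted p = 8.12e-09 (adjusted p = 0.385 with an estimated correlation). Cyc1, a subunit of complex III, rose by 0.42 ± 0.07 and Cox6c, of complex IV, by 0.59 ± 0.10. Of 14 glycolysis genes 9 rose and 1 fell, also when adjusted over the list alone: Pgam1 and Aldoa rose by 0.60 ± 0.10 and 0.51 ± 0.09 and the hexokinase gene Hk1 fell by 0.36 ± 0.06 (camera adjusted p = 0.00434, and adjusted p = 0.49 with an estimated correlation). Of 53 G2 and M phase genes 17 rose and 0 fell, also when adjusted over the list alone, with the checkpoint kinase gene Bub1 up by 0.40 ± 0.08 (edgeR Benjamini-Hochberg adjusted p = 0.00111, the highest of the genes named here; camera adjusted p = 0.000122, and adjusted p = 0.616 with an estimated correlation). S phase genes had 6 of 38 higher and 1 lower (4 and 0 adjusted over the list alone) and camera adjusted p = 0.024 (adjusted p = 0.617 with an estimated correlation, and 0.159 and 0.0802 without CreER knockout 1 and CreER control 4). Short genes were higher relative to long genes in LSK Mx1Cre knockout libraries 1, 3 and 4, with slopes of -0.101, -0.144 and -0.157 log2 CPM per doubling of exon length, while library 2 had 0.00795. The exons of oxidative phosphorylation genes had a median length of 816.5 bp against 2619 bp for all genes tested. With that trend removed the list of oxidative phosphorylation genes had camera adjusted p = 5.56e-09.

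Signalling lists were lower in knockout LSK cells. Of 17 STAT5 and cytokine response genes 7 fell and 2 rose (8 and 2 adjusted over the list alone), among them Stat5a by 0.53 ± 0.06, with camera adjusted p = 0.00809 (adjusted p = 0.385 with an estimated correlation). Of 16 immediate early genes 6 fell (9 adjusted over the list alone), with camera adjusted p = 0.00345 (adjusted p = 0.554 with an estimated correlation). Of 34 interferon-stimulated genes 9 fell, also 9 when adjusted over the list alone, with camera adjusted p = 0.00574 (adjusted p = 0.639 with an estimated correlation, 0.0568 without CreER control 3 and 0.0996 without CreER knockouts 2 and 3). Outside the lists, the nebulette gene Nebl had the largest rise of the ranked genes, 3.14 ± 0.25, and Phlda2 and Il22ra2 rose by 2.13 ± 0.26 and 1.87 ± 0.16. Nebl went from 0.843 ± 0.307 to 8.63 ± 1.38 CPM (SD) with CreER and from 1.81 ± 0.797 to 13.7 ± 5.96 with Mx1Cre. Large falls were those of Zfp970 (-3.29 ± 0.16), Gprasp2 (-3.26 ± 0.32), Pros1 (-3.13 ± 0.26) and Car12 (-3.00 ± 0.22). The edgeR test with Benjamini-Hochberg adjustment gave adjusted p of at most 9.89e-06 for the genes named here, reached by Phlda2. Zfp970, Pros1 and Car12 had called interaction terms (log2, Mx1Cre minus CreER) of -4.21, -3.67 and -3.11.

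Taken by Cre line, the knockout of LSK cells changed fewer genes with CreER than with Mx1Cre. With CreER, Nebl rose by 3.38 ± 0.38 and S100a8 by 2.54 ± 0.56, and Gprasp2 fell by 2.16 ± 0.38 (edgeR, Benjamini-Hochberg adjusted p of at most 0.0194). In all 445 genes were called with CreER, 221 higher and 224 lower. With Mx1Cre, Aoc1, a diamine oxidase gene, rose by 3.03 ± 0.52 and Nebl by 2.91 ± 0.34 (edgeR, Benjamini-Hochberg adjusted p of at most 0.000381). Kcnj5 and Slc6a15 had no count in the 4 Mx1Cre knockout libraries, against 4.29 ± 1.21 and 1.85 ± 0.266 CPM (SD, n = 4) in controls, which puts them at least 76.3-fold and 33-fold lower. Here 4378 genes were called, 2141 higher and 2237 lower, and 853 against a fold of 1.5, 101 higher and 752 lower. The CreER count depended on single libraries: it was 714 without knockout 1, 164 and 196 without knockouts 2 and 4, and 235, 159 and 215 without controls 1, 2 and 4. Sex-linked genes of LSK CreER knockout libraries 2 and 3 went against their labels. Both are knockouts, so an exchange between them would leave the groups compared here unchanged. With them exchanged and sex as a covariate 467 genes were called. Without both of them, which also lowers the number of knockout libraries, 33 genes were called. The DESeq2 test called 889 genes with CreER, the fit of the 8 compared libraries alone 231, and the test against a fold of 1.5 called 6.

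**Figure D2:**
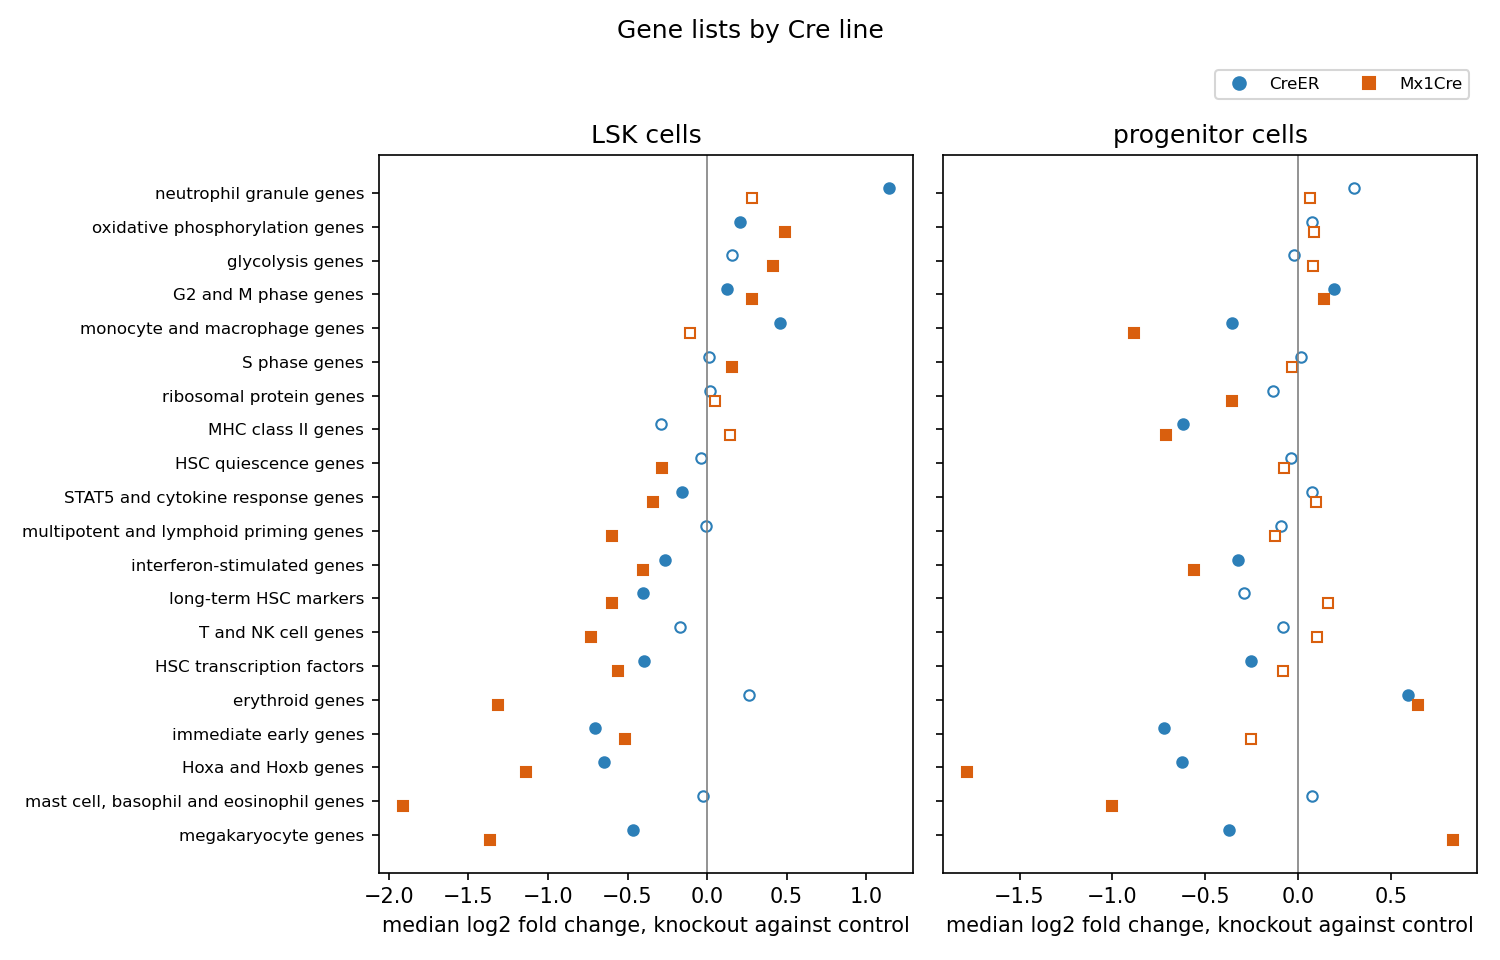
Median log2 fold change, knockout against control, of the gene lists called over both Cre lines in at least 1 cell population. Circles are CreER and squares Mx1Cre, filled where camera with the preset correlation called the list in that Cre line; in LSK cells the megakaryocyte list had medians of -0.47 and -1.37.

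The knockout effect in LSK cells differed between the Cre lines for 616 genes, tested as an interaction, of which 519 were lower with Mx1Cre. The knockout effects on Zfp970, Marcks, Adcy6 and Ica1 were lower with Mx1Cre than with CreER, by interaction terms of -4.21 ± 0.32, -3.33 ± 0.28, -2.99 ± 0.27 and -2.33 ± 0.18 (log2, SE). Slc6a9, a glycine transporter gene, and Etv5 differed in the other direction, by 2.26 ± 0.31 and 1.36 ± 0.21. The edgeR test with Benjamini-Hochberg adjustment gave adjusted p of at most 0.000986 for these genes. Log2 fold changes of the Cre lines correlated across the 14102 genes (Pearson r = 0.425, Spearman rho = 0.379), where genes are not independent replicates. Of the genes called in both, 120 were higher and 177 lower in both, against 33.6 and 35.5 for independent lists, and 3 were opposite. The count of 616 was 2556 without Mx1Cre knockout 2, and 403, 319 and 392 without Mx1Cre knockouts 1, 3 and 4. It was 388 and 334 without Mx1Cre controls 1 and 2 and 386 without CreER knockout 3. Without both LSK CreER knockouts 2 and 3 it was 310, and with the DESeq2 test 1229.

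In knockout progenitor cells, genes that fell included Hoxa genes and some of monocytes, and genes that rose a few of erythroid cells. Of the 8 gene lists that camera called with the preset correlation, 0 were called with an estimated correlation. Hoxa9, Hoxa7 and Hoxa3 fell by 1.78 ± 0.16, 1.83 ± 0.21 and 1.67 ± 0.31 (log2, SE) over both Cre lines. Ccr2, a chemokine receptor gene of monocytes, fell by 1.35 ± 0.13, from 115 ± 27.9 to 46.4 ± 8.01 CPM (SD) with CreER and from 223 ± 26.5 to 87 ± 14.9 with Mx1Cre. Alas2, of heme synthesis in erythroid cells, rose by 1.75 ± 0.43 and Tfrc, the transferrin receptor gene, by 0.39 ± 0.10. The edgeR test with Benjamini-Hochberg adjustment gave adjusted p of at most 0.0189 for these genes. In all 1067 of 13692 genes were called, 312 higher and 755 lower, and 249 against a fold of 1.5, 40 higher and 209 lower. Leaving out Mx1Cre control 1 raised the count to 1794.

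All 5 called of 10 Hoxa and Hoxb genes fell, also 5 when adjusted over the list alone (camera adjusted p = 5.64e-06, and adjusted p = 0.182 with an estimated correlation). Of 18 monocyte and macrophage genes 7 fell and 1 rose (11 and 1 adjusted over the list alone), among them Irf8 (-1.45 ± 0.17), a factor of monocyte and dendritic cell fate, Klf4 (-1.66 ± 0.26) and Ms4a6c (-1.01 ± 0.14), with camera adjusted p = 7.94e-05 (adjusted p = 0.635 with an estimated correlation). Of 10 MHC class II genes 2 fell, also 2 when adjusted over the list alone, namely H2-DMa (-1.01 ± 0.17) and H2-DMb1 (-0.66 ± 0.12), which act in peptide loading, with camera adjusted p = 0.00342 (adjusted p = 0.635 with an estimated correlation). Of 34 interferon-stimulated genes 7 fell (18 adjusted over the list alone), Ifi44 by 1.86 ± 0.34 and Mx2 by 1.57 ± 0.31 (edgeR, Benjamini-Hochberg adjusted p = 0.00415, the highest of the genes named here), with camera adjusted p = 8.99e-06 (adjusted p = 0.635 with an estimated correlation). Of 21 erythroid genes 3 rose (4 adjusted over the list alone), with camera adjusted p = 1.93e-07 (adjusted p = 0.635 with an estimated correlation). Progenitor Mx1Cre control 1 stood apart from its group, with the steepest length slope of all libraries, -0.362. Knockout 4 of the same Cre line had -0.296.

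G2 and M phase genes were called as a list with 1 of 53 genes, Bub1, past the test (0.44 ± 0.10), also 1 when adjusted over the list alone, and camera adjusted p = 3.98e-05 (adjusted p = 0.728 with an estimated correlation). Ribosomal protein genes had a median of -0.25 and 0 of 34 past the edgeR test, also 0 when adjusted over the list alone, with camera adjusted p = 0.00752 (adjusted p = 0.95 with an estimated correlation, 0.542 without Mx1Cre control 1 and 0.0529 without CreER control 4). With Mx1Cre alone the median turned to 0.049 without that Mx1Cre control. Of 16 immediate early genes 1 fell, also 1 when adjusted over the list alone, with camera adjusted p = 0.00964 (adjusted p = 0.728 with an estimated correlation, and 0.0529 without CreER control 4). Of 20 neutrophil granule genes 2 fell, also 2 when adjusted over the list alone, Elane, the neutrophil elastase gene, by 0.89 ± 0.22 (edgeR, Benjamini-Hochberg adjusted p = 0.0205, the highest of the genes named here) and Gstm1 by 0.66 ± 0.16, and the list was not called (camera adjusted p = 0.627). The survival gene Bcl2 fell by 0.79 ± 0.16. Outside the lists, Nebl rose by 2.64 ± 0.31 and Arhgef40 by 1.01 ± 0.11. Ppic, Ica1, Bhlha15, Gspt2, Scarf1 and Fkbp9 fell by 3.24 ± 0.20, 2.84 ± 0.14, 2.79 ± 0.33, 2.69 ± 0.14, 2.42 ± 0.20 and 2.02 ± 0.13. Of these, Ppic, Ica1, Gspt2 and Fkbp9 had called interaction terms (log2, Mx1Cre minus CreER) of -2.75, -3.13, -3.24 and -2.16. Oxidative phosphorylation genes were not called (camera adjusted p = 0.0903, and adjusted p = 0.95 with an estimated correlation), but were with the gene length trend removed and the preset correlation (adjusted p = 0.000951).

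With CreER, 23 genes were called in progenitors, 5 higher and 18 lower, among them Bhlha15 (-2.85 ± 0.45), Mdfi (-1.89 ± 0.29) and Nebl (2.34 ± 0.43), with edgeR Benjamini-Hochberg adjusted p of at most 0.0394. With Mx1Cre, 833 were called, 218 higher and 615 lower, with Aoc1 and the collagen gene Col4a1 up by 3.96 ± 0.45 and 3.76 ± 0.39 (edgeR, Benjamini-Hochberg adjusted p of at most 4.96e-05). Map7d3 had no count in the 4 Mx1Cre knockout libraries against 7.19 ± 1.01 CPM (SD, n = 4) in controls, at least 101-fold lower. Tnfsf4 had no count in the controls against 0.534 ± 0.369 CPM in knockouts, at least 7.78-fold higher. The CreER count was 11, 7 and 9 without CreER knockouts 2, 3 and 4, 10, 15 and 7 without CreER controls 1, 2 and 3, and 78 without Mx1Cre control 1. It was 183 with the DESeq2 test and 158 with the 8 libraries alone. The Mx1Cre count was 553 without knockout 1 and 1541 without control 1, and 344 with the 8 libraries alone. Between the Cre lines the effect differed for 41 genes, 9 higher and 32 lower with Mx1Cre, such as Trp53i11 (2.44 ± 0.35), Col4a1 (3.50 ± 0.54), Zfp970 (-4.73 ± 0.37), Ica1 (-3.13 ± 0.27) and Gspt2 (-3.24 ± 0.28), with edgeR Benjamini-Hochberg adjusted p of at most 0.0068. That count was 25 without CreER control 1 and 25 without CreER control 4. It was 120 with the DESeq2 test, 19 with limma-voom and 62 with the gene length trend removed. Log2 fold changes of the Cre lines correlated across 13692 genes (Pearson r = 0.541, Spearman rho = 0.512), with 2 genes higher and 18 lower in both, against 0.1 and 0.8 for independent lists, and 1 opposite.

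The knockout effect differed between LSK and progenitor cells for 364 of 14459 genes, 159 higher and 205 lower in LSK cells. With the mouse as a block it differed for 769, 398 higher and 371 lower, and for 877, 474 higher and 403 lower, with LSK CreER knockouts 2 and 3 exchanged, which did not match the progenitor libraries of their labelled mice. Ccr2 and Tmem119 differed by 1.24 ± 0.18 and 1.18 ± 0.16 (log2, SE), with Ccr2 lower in knockout progenitors. Mfsd2b, Adcy6 and Tom1l1 differed by -2.26 ± 0.28, -2.38 ± 0.30 and -1.73 ± 0.21, and Ica1 by 0.97 ± 0.15. The edgeR test with Benjamini-Hochberg adjustment gave adjusted p of at most 0.000406 for these. Megakaryocyte genes differed as a list, with 7 of 17 lower in LSK cells, also 7 when adjusted over the list alone, and a median of -1.05 (camera adjusted p = 1.02e-08, and adjusted p = 0.0148 with an estimated correlation). That median is a mean over Cre lines that differed. In progenitors the knockout effect on the list was higher with Mx1Cre than with CreER, by a median of 1.19 (camera adjusted p = 0.00609 with an estimated correlation). Of genes called over both Cre lines, 161 were higher and 501 lower in both populations, against 42 and 103.4 for independent lists, and 13 were opposite. LSK and progenitor libraries came from the same mice. The count of 364 was 197 and 176 without the CreER knockout mice 2 and 4, 204 and 227 without the CreER control mice 2 and 4, 166 without Mx1Cre knockout mouse 1 and 202 without Mx1Cre control mouse 4. It was 640 without progenitor Mx1Cre control 1 and 148 without LSK CreER knockouts 2 and 3.

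Controls of the Cre lines also differed, which bears on every comparison between Cre lines. In LSK cells interferon-stimulated genes were lower in Mx1Cre than in CreER controls for 33 of 34, also 33 when adjusted over the list alone, with a median of -2.67 (camera adjusted p = 7.12e-39, and adjusted p = 0.0953 with an estimated correlation). Irf7, an interferon regulatory factor, had 311 ± 89.1 CPM (SD) in CreER and 14.5 ± 3.44 in Mx1Cre controls, a log2 difference of -4.39 ± 0.25 (SE). Rtp4, Oas3 and Lgals3bp were lower by -3.93 ± 0.28, -3.66 ± 0.26 and -1.67 ± 0.10, and Fn1, Rassf4 and Cyth1 higher by 4.94 ± 0.44, 1.67 ± 0.15 and 0.84 ± 0.07 (edgeR, Benjamini-Hochberg adjusted p of at most 1.02e-06). Of 21 p53 target genes 12 were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 5.67e-06, and adjusted p = 0.0953 with an estimated correlation). All 20 neutrophil granule genes were higher in Mx1Cre controls, also when adjusted over the list alone (camera adjusted p = 7.93e-11, and adjusted p = 0.268 with an estimated correlation). In all 3054 genes differed, 1643 higher and 1411 lower. In progenitors 3458 differed, 1959 higher and 1499 lower. There 32 of 34 interferon-stimulated genes were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 1.43e-25, and adjusted p = 0.0761 with an estimated correlation).

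Of 21 p53 target genes 13 were lower in Mx1Cre than in CreER progenitor controls, also 13 when adjusted over the list alone (camera adjusted p = 5.15e-09, and adjusted p = 0.0454 with an estimated correlation). Ccng1, a p53 target, and Dhx58, an RNA sensor gene, were lower by -1.45 ± 0.10 and -2.54 ± 0.18 (log2, SE), while Smpdl3a, Pld4 and Psap were higher by 2.03 ± 0.18, 2.32 ± 0.22 and 1.75 ± 0.18 (edgeR, Benjamini-Hochberg adjusted p of at most 1.44e-05). Of 14 megakaryocyte genes 10 were lower, also 10 when adjusted over the list alone, with camera adjusted p = 1.08e-07 (adjusted p = 0.0454 with an estimated correlation).

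LSK and progenitor controls differed for 5006 of 14459 genes, 2511 higher and 2495 lower in LSK cells. That fit left out that each mouse gave both libraries. With the mouse as a block 5619 genes differed, 2840 higher and 2779 lower. Long-term HSC markers were higher in LSK cells for 19 of 20, also 19 when adjusted over the list alone, with a median of 1.97 (camera adjusted p = 2.12e-18, and 0.00283 with an estimated correlation). Erythroid genes were lower for 19 of 21 and neutrophil granule genes for 19 of 20, also 19 each when adjusted over the list alone (camera adjusted p = 4.27e-10 and 7.37e-08, and adjusted p = 0.148 and 0.164 with an estimated correlation).

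**Figure D3:**
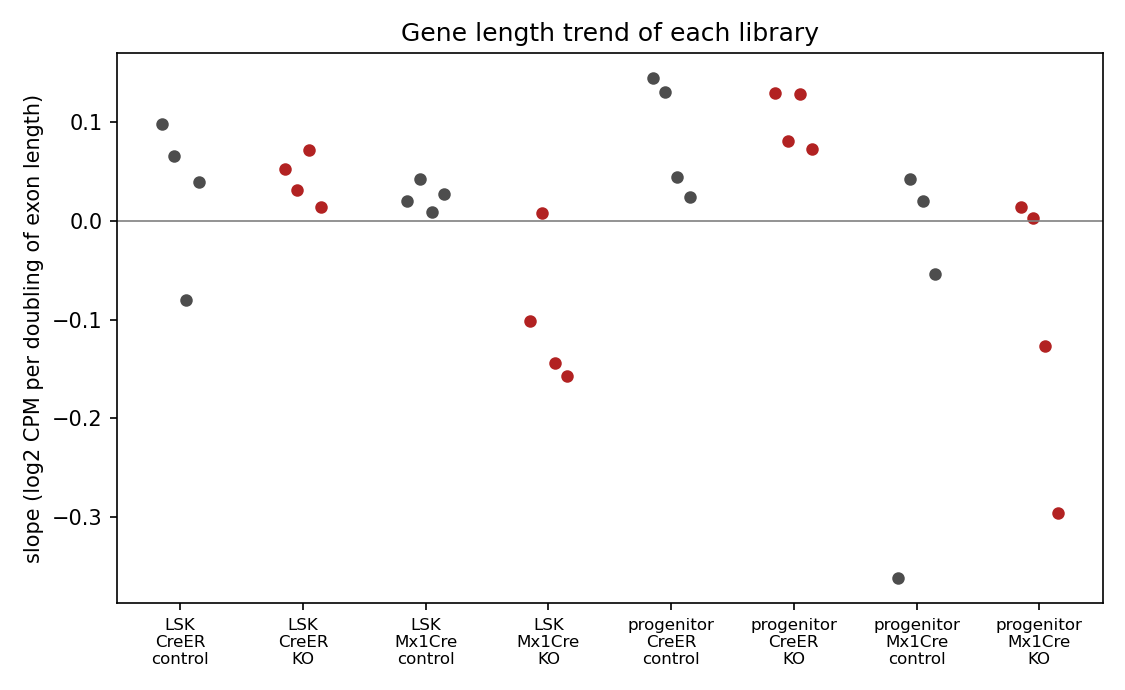
Gene length trend of each library, as the slope of its log2 CPM deviation from the mean of its cell population per doubling of exon length. Points are libraries; progenitor Mx1Cre control 1 lies lowest at -0.362, and 3 LSK Mx1Cre knockouts lie between -0.157 and -0.101.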

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

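Tests on Kat7 left after deletion, on the Mx1Cre knockout libraries alone, on single control mice, on cells of another type, monocytes and neutrophils and on the Cre line, treatment or cohort were chosen after the result was seen, as were list tests outside knockout against control, the removal of the gene length trend, the splits that part pairs and the account of which libraries a split relabelled. The splits, the test of spread and the bounds for the length tests were set before those values were seen.

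Single libraries lay far from the other 3 of their group in 3 of 96 groups of values examined, and chance alone marks about 1 in 20. The 10 most counted genes took 7.18% of counts in progenitor Mx1Cre control 4, against 5.98% to 6.16% in the others. Kat7 was 63.7 CPM in LSK Mx1Cre control 4 against 72.3 to 73.5. Nebl was 5.42 CPM in progenitor Mx1Cre control 2 against 1.19 to 1.75.

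The knockout effect in LSK cells differed between Cre lines for 616 genes, by the interaction test of edgeR. Among named genes the interaction terms (log2, Mx1Cre minus CreER) were -0.74 for Hoxa9, -1.57 for Gfi1b, -2.61 for Tek, -0.80 for Eng, -2.03 for Robo4 and -1.87 for Gata1. They were -3.28 for Car1, -1.57 for Il1rl1, -4.21 for Zfp970, -3.67 for Pros1, -3.11 for Car12, -2.33 for Ica1, -3.33 for Marcks and -2.99 for Adcy6. Slc6a9 (2.26) and Etv5 (1.36) went the other way. Kcnj5 (-7.77) and Slc6a15 (-6.61) had no count in Mx1Cre knockouts, so their fitted terms depend on the prior count. In progenitors 41 genes differed, among them Ppic (-2.75), Ica1 (-3.13), Gspt2 (-3.24), Fkbp9 (-2.16), Zfp970 (-4.73), Col4a1 (3.50) and Trp53i11 (2.44). Map7d3 (-8.29) had no count in Mx1Cre knockouts. The megakaryocyte list differed by a median of 1.19 in progenitors (camera adjusted p = 0.00609 with an estimated correlation).

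Between LSK and progenitor cells the effect differed for 364 genes. Terms (log2, LSK minus progenitors) were -1.61 for Gfi1b, -1.88 for Egr1, -1.05 for Itga2b, -1.63 for Gata1, -1.73 for Il1rl1, -0.46 for Stat5a, -1.25 for Col4a1, -2.38 for Adcy6, -1.73 for Tom1l1 and -2.26 for Mfsd2b. They were 0.78 for Hoxa7, 0.60 for Pgam1, 1.24 for Ccr2, 1.15 for Irf8, 1.05 for Ms4a6c, 0.88 for Gstm1, 0.85 for Ppic, 0.97 for Ica1, 0.94 for Mdfi and 1.18 for Tmem119. Tnfsf4 (-2.46) had no count in progenitor Mx1Cre controls. The megakaryocyte list differed by a median of -1.05 (camera adjusted p = 0.0148 with an estimated correlation).

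Oxidative phosphorylation genes were higher in knockout LSK cells, with a median of 0.378 on the log2 CPM scale. With the gene length trend removed the median was 0.269 and the list was still called (camera adjusted p = 5.56e-09, within a range of 7.37e-11 to 0.385 over its alternatives, the highest with an estimated correlation), which argues against the trend as the whole cause. RNA or library differences of the Mx1Cre knockouts alone stay open: the median was 0.207 with CreER, between the bounds set for either answer, and 0.491 with Mx1Cre. A higher level of these genes in cells without Kat7 remains a hypothesis, and a part of the rise with Mx1Cre may be technical.

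The knockout effect was smaller with CreER than with Mx1Cre in LSK cells. Less complete deletion is argued against by Kat7 itself, with 1.26% left with CreER and 1.9% with Mx1Cre. A larger spread between CreER libraries would leave the slope of CreER on Mx1Cre fold changes near 1 once sampling noise is taken out, but it was 0.288, and 0.248 to 0.33 without any 1 CreER library. The gene length trend is argued against as the whole cause by the calls it left: with it removed 480 of the 616 genes kept their call, and 586 were called in all. Cre line, treatment and mouse cohort cannot be told apart, since each Cre line has its own, and their controls differed for 3054 genes.

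Interferon-stimulated and p53 target genes were higher in CreER than in Mx1Cre controls. A few aberrant mice are argued against: the lowest CreER control exceeded the highest Mx1Cre control by 1.74 or more in the mean log2 CPM of the interferon list in both cell populations, and by 0.48 or more for the p53 list. Monocytes and neutrophils in the sort are argued against by their lists, whose medians went the other way in LSK cells (1.32 and 2.64, against -2.67 for the interferon list). Cells of another type stay open, although the lineage-negative, Sca-1 and Kit positive gate would mostly remove mature cells: the dendritic, monocyte and T or NK lists had a joint median of 0.75, but of 14 T and NK genes 2 were higher and 3 lower, of 15 mast cell, basophil and eosinophil genes 3 higher and 4 lower, and plasma cells were not tested. The p53 list had a median of -0.635 in LSK cells, and for both lists Cre line, treatment and cohort cannot be told apart.

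Other splits of the same libraries were refitted. In LSK cells 1 of 35 splits, the real one, gave as many genes with CreER (445, highest other 179) and between controls (3054, highest other 0), so chance is excluded there. With Mx1Cre it was also 1 of 35 (4378, highest other 2), but same-numbered LSK Mx1Cre libraries deviated together, and the 8 splits that part all 4 such pairs (highest other 0) are too few for a share under 0.05. The splits that part fewer pairs gave at most 2 genes. In progenitors chance is excluded between controls of the Cre lines, with 1 of 35 splits (3458, highest other 85). With CreER the rank was also 1 of 35 (23, highest other 0). Kat7, the deleted gene, is among those 23 and alone exceeds 0, so this rank does not test the other genes. Over both Cre lines, chance with no knockout effect in either line is also excluded. In LSK cells 1 of 100 splits, the real one, reached 3927 (highest other 3240, and 3293 among splits that part the pairs). In progenitors it was 1 of 100 as well (1067, highest other 495). Splits that keep or exchange all Mx1Cre labels hold the Mx1Cre knockout effect, so these ranks do not test an effect shared by both Cre lines. Between LSK and progenitor controls chance is excluded, with 1 of 100 (5006, highest other 1801, and 3052 among splits that part the libraries of each mouse). The difference between cell populations was reached by 2 of 100 splits with both libraries of a mouse kept together (364, highest other 379). Among splits that part the same-numbered Mx1Cre mice the highest other was 138. Those splits also scramble the knockout effect that both populations share. They therefore do not test an equal effect in both, and cannot exclude chance for that difference. The difference between Cre lines in LSK cells was reached by 4 of 100 splits (616, highest other 2599), and by 11 of 100 that part the pairs (highest other 3188). These splits cannot decide on chance there, since any split that keeps or exchanges all Mx1Cre labels holds the Mx1Cre knockout effect. That difference in progenitors was reached by 5 of 100 splits (41, highest other 236), which have the same limit. Chance is not excluded for Mx1Cre in progenitors, with 3 of 35 (833, highest other 2810). Among the first 100 splits, each other split that reached the real difference between Cre lines left all 8 Mx1Cre libraries with their real labels or with knockout and control exchanged, so it holds the Mx1Cre knockout effect. The split with 2810 points to a structure of the samples: it set controls 1 and 4 and knockouts 3 and 4, the Mx1Cre progenitor libraries with negative length slopes, against the other 4. With the gene length trend removed 809 of the 833 genes kept their call.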

How the results depend on the processing

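Removal of the length trend, omission or exchange of LSK CreER knockouts 2 and 3, omission of progenitor Mx1Cre control 1 and some settings for correlations were chosen after the data were examined, and the other alternatives before. Where fewer libraries or a stricter null do not show it, the cause was not tested. The DESeq2 test called 889 genes for LSK CreER, 183 and 1264 for progenitor CreER and Mx1Cre, 1229 and 120 for the difference between Cre lines in LSK cells and progenitors, and 611 for that between cell populations. Against a fold of 1.5 the counts were 6 and 853 for LSK CreER and Mx1Cre, 530 over both, and 2, 312 and 249 in progenitors. With the 8 compared libraries alone they were 231 for LSK CreER and 158 and 344 for progenitor CreER and Mx1Cre. limma-voom gave 36 for progenitor CreER and 19 for the Cre difference there. With the length trend removed these were 74 and 62, and the difference between cell populations 566. Without LSK CreER knockouts 2 and 3 counts were 33 for LSK CreER, 310 for the LSK Cre difference and 148 between populations, and the median of the interferon list with CreER turned to 0.008. Without progenitor Mx1Cre control 1, 640 genes differed between populations, and the ribosomal protein list with Mx1Cre turned to 0.049, the highest value with 1 library left out (lowest -0.449). The mouse as a block (pairing LSK with progenitor libraries) gave 769 between populations, 877 with the libraries exchanged and 1236 with control mouse 1 also omitted; the replicate block gave 4221 for LSK Mx1Cre, against 4378, and changed no headline count by over 1.5 times. With an estimated correlation camera called 0 lists in LSK cells and 0 in progenitors (2 and 1 at an unadjusted p under 0.05), where fry called 15 and 4. The correlation of Cre lines in LSK cells was 0.39 with DESeq2, 0.337 without knockouts 2 and 3, 0.589 over genes called in either and 0.166 without a filter, and in progenitors 0.646 and 0.198 for the last pair of settings. Leaving out 1 library at a time gave 159 to 714 genes for LSK CreER, 3157 to 5674 for LSK Mx1Cre, 3113 to 4897 over both, 319 to 2556 for the Cre difference and 2107 to 3554 for controls. In progenitors the ranges were 7 to 78, 553 to 1541, 775 to 1794, 25 to 60 and 2316 to 3753. Leaving out 1 mouse gave 166 to 538 between populations (197, 176, 204, 227, 166 and 202 for CreER knockout mice 2 and 4, CreER control mice 2 and 4, Mx1Cre knockout mouse 1 and Mx1Cre control mouse 4) and 3961 to 5193 for LSK against progenitor controls. Correlations ran from 0.36 to 0.423 and 0.455 to 0.531, and called lists from 15 to 16 and 8 to 10. Of the named genes 0 changed direction under any alternative where they were called before or after the change. Changes of direction in genes called in neither were not counted. With 1 library or mouse left out 295 of their values lost and 45 gained a call. Under the other alternatives 169 lost and 47 gained one. For gene lists 61 lost and 48 gained a call with 1 library or mouse left out, and 125 lost and 17 gained one otherwise. Depth limits small changes: among the 50 of 100 simulated genes with lower expression, 76% of 1.5-fold changes were recovered in the LSK comparison over both Cre lines and 30% with CreER alone, against 98% and 82% among the other 50. Genes below a mean of 3 log2 CPM were not simulated as changed.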

Other observations

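The axis from LSK to progenitor controls and the genes near Kat7 were tested with bounds set before the values were seen, and the list results below come from lists fixed before the data were examined.

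Further lists were not called in knockout LSK cells. Of 13 BCL2 family genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.156). Of 21 p53 target genes 4 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.322). Replication origin licensing genes had 4 of 17 higher and 1 lower (camera adjusted p = 0.125), and ribosome biogenesis genes 5 of 20 higher (camera adjusted p = 0.121), with the same counts when adjusted over the list alone. Ribosomal protein genes had 2 of 34 lower (0 adjusted over the list alone; camera adjusted p = 0.87). MHC class II genes had 1 of 10 higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.245). Dendritic cell genes had 1 of 10 higher and 1 lower, also when adjusted over the list alone (camera adjusted p = 0.768). B cell genes had 1 of 13 higher and 1 lower (0 and 1 adjusted over the list alone; camera adjusted p = 0.817), and endothelial and stromal genes 1 of 3 lower (2 adjusted over the list alone; camera adjusted p = 0.211). The HBO1 subunit list had a median of 0.02 and a mean of -0.54 in LSK cells, where the test pointed down, and 0.10 and -0.48 in progenitors, where it pointed up.

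Sex-linked genes of LSK CreER knockout libraries 2 and 3 went against their labels: library 2, labelled female, had 0.741 CPM of Xist and 90.1 of Ddx3y, and library 3, labelled male, had 3351 and 0.164. Their progenitor counterparts matched the labels, and Kat7 was 0.855 and 0.82 CPM in the LSK libraries, both labelled knockout. An exchange of these LSK libraries would leave the groups compared unchanged and would alter only fits that use sex, mouse or replicate number.

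Expression differences linked to the floxed locus were tested as a hypothesis. Of 103 genes within 5 Mb of Kat7, 25.2% were called in LSK cells over both Cre lines, against 27.9% elsewhere (Fisher's exact test, two-sided p = 0.659), which argues against an excess there.

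A shift of knockout LSK cells toward the progenitor profile was tested as a hypothesis, as a share of the distance from LSK to progenitor controls. With Mx1Cre the knockouts lay 0.351 above the controls (two-sided exact permutation p = 0.0286, the smallest possible for 4 against 4). That test leaves out that same-numbered LSK Mx1Cre libraries deviated together; the 16 exchanges within such pairs gave a two-sided exact permutation p = 0.125, the smallest they allow, in a test added after the result was seen. With CreER the difference was 0.156 (exact permutation p = 0.143) and the scores overlapped, with 0.11 for the lowest knockout and 0.168 for the highest control. The bound asked for separation in both Cre lines, which was not met, so the hypothesis as set fails; a shift with Mx1Cre alone may remain, and the length trend of those libraries was not removed from it.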
